A study of Mus musculus with 2 samples.

How the data were processed

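PolyA RNA of mouse E14 embryonic stem cells labelled as a double knockout of Ago1 and Ago2 was profiled in 2 libraries of 1 group, numbered as in the labels. Per the labels' protocols, RNA was extracted with Trizol and libraries were made from 1 ug of total RNA with a TruSeq kit by a reverse-stranded protocol. Per the submitters' processing notes, STAR 2.4.2a and the mm10 (GRCm38) build were used. The deposited files hold raw counts, whole-number read counts per Ensembl gene in 1 column, per the file contents. The counting tool, its strand setting, its treatment of reads that map to several or overlapping genes and the annotation release are not given in the sources used here. Antisense and overlapping genes may therefore share reads, and members of gene families may lose or split them.

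The files listed 47643 gene IDs, of which 47224 were named with GENCODE M21, an annotation of the same build that also gave positions, exon lengths and GC content. The other 419 IDs took 0.116% of counts in replicate 1 and 0.124% in replicate 2, and stayed in the library totals. Protein-coding genes took 96.9 and 96.8% of counts, mitochondrial genes 3.03 and 3.08%, the 82 ribosomal protein genes 7.23 and 6.98%, and the 20 most abundant genes 9.02 and 8.73%. A gene had a count in 24860 and 24325 cases. Totals were 34798975 and 29789560 counts, so 1 count equals 0.0287 and 0.0336 CPM.

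CPM was computed on the library total of gene counts, and a gene was called expressed at 1 CPM in both libraries. For list levels, the median log2(CPM + 1) per library was averaged and placed among 10000 random lists of the same size drawn from protein-coding genes. Intervals are 95% exact Poisson intervals for CPM and 95% Clopper-Pearson intervals for shares. TPM, used as an alternative, was computed from the counts and exon lengths.

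With 1 genotype, no test between genotypes was possible. Replicate 2 was compared with replicate 1 by a two-sided exact binomial test per gene at library sizes scaled by edgeR's TMM factors (0.999 and 1.00), with Benjamini-Hochberg adjustment over genes with at least 10 counts in total and a threshold of 0.05. Log2 ratios used a pseudocount of 0.5 counts. As an alternative, edgeR's exact test used a trended dispersion estimated with both libraries as 1 group. That dispersion contains the differences it is set against, so this test calls few genes. For lists, the median log2 ratio was placed among 10000 random lists matched on mean expression in 20 bins, with no p-value across genes. Log2 ratios were also recomputed after removing a lowess trend (fraction 0.3) on GC content and length; across genes the Spearman rho with GC content was -0.28 and with length 0.05, and 99.5% of tested genes had a value. The share of 50-base stretches of a gene's transcripts found in other genes marked genes with uncertain counts.

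The 23 gene lists, with 366 symbols of which 361 were found, the groups, the tests and the rule for named genes were fixed before the data were examined. The lists hold Argonaute, microRNA pathway, PIWI pathway, core, naive and primed pluripotency, 2-cell-like, extraembryonic endoderm, trophoblast, mesoderm, definitive endoderm, neuroectoderm, germ line, fibroblast, miR-290 target, let-7 target, p53 and apoptosis, cell cycle, DNA methylation and Polycomb, imprinted, interferon response, housekeeping and adult tissue genes. Zscan4a, Eif1ad8, Dub1, Dux and Psx1 were not found. The Argonaute list itself had a median log2(CPM + 1) of 5.84 ± 0.34 with 3 of 4 expressed (percentile 95.9, or 79.5 in TPM). The rule named Ago1 to Ago4, the 3 highest and 2 lowest members of each list, the 15 most abundant genes, and per direction the 6 genes with the largest ratio among called genes with at least 100 counts; the text gives only a part of the genes so named, and the others are not reported here. Nnat and the genes at the end of chromosome 3 were chosen after their values were seen.

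The tests were run on counts simulated from the libraries' own means and sizes, with 200 genes changed. With sampling noise only, over 19088 genes, the binomial test recovered 71.6, 98.5 and 100% of genes changed 1.5-fold, 2-fold and 4-fold and called 7 unchanged genes. With the spread seen between these libraries added, over 19076 genes, it called 5485 unchanged genes, while edgeR's exact test called 0 and recovered 2.99, 40.3 and 100%. With a simulated GC trend, over 19049 genes, the binomial test called 5620 unchanged genes before and 8 after removal of the trend. The list test was run only on the simulation with sampling noise alone. There, of 200 simulated unchanged lists 4% fell outside the central 95%, and a list lowered by 0.5 lay at percentile 0. Genes varied independently in it, so it does not show how the percentiles behave with the spread of these libraries or with related genes. Alternatives were DESeq2 size factors, totals without TMM, other count filters, expression thresholds and pseudocounts, TPM, means in place of medians, and each library alone. Software was edgeR 4.0.16 and DESeq2 1.42.0 in R 4.3.3, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.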

Results

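Messenger RNA was sequenced from mouse embryonic stem cells of the E14 line, derived from blastocysts of the 129/Ola background, labelled as a double knockout of Ago1 and Ago2. These genes encode Argonaute proteins, which bind microRNAs and carry out the repression of their target transcripts. The series held 2 libraries of this 1 genotype, named here replicate 1 and replicate 2. Total gene counts were 34798975 in replicate 1 and 29789560 in replicate 2. Cells were grown in 15% serum with 100 U/mL LIF, a cytokine that holds these cells in self-renewal, on plates coated with 0.2% gelatine. Unmodified cells were not analysed here, so no value below measures an effect of the knockout. Levels are given in CPM, a gene's count scaled to a common library total, as mean ± SD over the 2 libraries (n = 2) unless a replicate is named. CPM is not scaled to gene length, so rankings by level below are of reads and can differ in TPM. At this depth 3 counts, taken as the floor, equal 0.0862 CPM in replicate 1 and 0.101 CPM in replicate 2. The labels do not say whether the libraries came from separate cultures or clones, so the SDs measure only the spread between these samples, which may be technical. P-values of the exact binomial test weigh a difference against counting error only. Those of edgeR's exact test use a dispersion estimated from these same libraries. Intervals and floors cover counting error only.

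The first question was what the libraries held at the targeted genes. Reads were assigned to Ago1 and Ago2 in both libraries, and Ago1 differed between them. Ago1 (ENSMUSG00000041530; GRCm38 chromosome 4, 126435012 to 126468583, minus strand) stood at 70.8 CPM (95% interval 68.0 to 73.6) in replicate 1 and 141 CPM (95% interval 137 to 145) in replicate 2, from 2463 and 4205 counts. Ago2 (ENSMUSG00000036698; chromosome 15, 73095844 to 73184935, minus strand), the member of the family with slicer activity, stood at 124 CPM (95% interval 120.0 to 127) and 129 CPM (95% interval 125 to 133). Ago3 (ENSMUSG00000028842; chromosome 4, 126331704 to 126429556, minus strand) was lower, with 33.2 ± 1.69 CPM. Ago4 (ENSMUSG00000042500; chromosome 4, 126489541 to 126533472, minus strand) had 26 and 18 counts, or 0.676 ± 0.101 CPM. Ago1 and Ago2 together took 85.6% of Argonaute counts in replicate 1 (exact Clopper-Pearson 95% interval 84.8 to 86.4%) and 88.5% in replicate 2 (87.9 to 89.2%), a mean of 87.1% ± 2.08. Ago1 was higher in replicate 2 by a log2 ratio of 0.99 ± 0.04 (counting SE), with an adjusted p of 6.69e-166 in the two-sided exact binomial test and 1.37e-08 in edgeR's exact test with the spread of these libraries. The log2 ratio was 0.06 ± 0.03 for Ago2, with an adjusted p of 0.207 in the exact binomial test. Counts per gene sum all exons, so they do not show an edited exon or a frameshift, and these levels check no genotype label. Exons of Ago2 overlap those of another annotated gene.

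**Figure D1:**
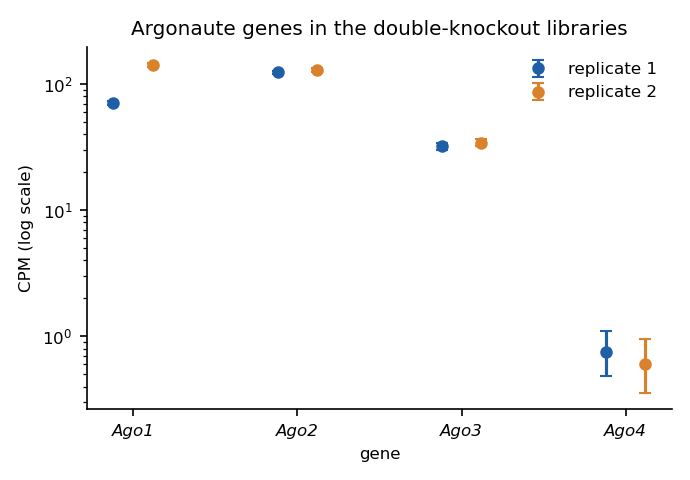
Level in CPM (log axis) of Ago1, Ago2, Ago3 and Ago4 in replicate 1 (blue) and replicate 2 (orange), with exact Poisson 95% intervals as bars. Ago1 lies at 70.8 CPM in replicate 1 and 141 CPM in replicate 2, while the Ago2 points lie at 124 and 129 CPM.

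All 23 measured genes of the microRNA pathway list reached 1 CPM in both libraries. Their median log2(CPM + 1) was 7.39 ± 0.0045, at percentile 100 of 10000 random lists of protein-coding genes. The chaperone genes Hsp90ab1 (6381 ± 312 CPM) and Hspa8 (4072 ± 107 CPM), whose products take part in loading Argonaute, and the nuclear transport gene Ran (848 ± 44.8 CPM) were the most abundant members. Of the Hspa8 sequence, 38.6% recurs in other genes. Lin28b, a repressor of let-7 processing, stood at 48.9 ± 2.15 CPM, and Prkra, which encodes a Dicer partner, was the lowest at 16.1 ± 0.0824 CPM. Of the PIWI pathway genes, which act mainly in germ cells, 9 of 12 reached 1 CPM, with a median of 1.80 ± 0.06 (percentile 39.1). Piwil2 (42.8 ± 3.72 CPM), Mael (18.6 ± 3.50 CPM) and Mov10l1 (12.1 ± 3.01 CPM) were its most abundant members, and Asz1 had no count.

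The state of the cells was read from pluripotency and lineage lists. All 16 core pluripotency genes were expressed, with a median log2(CPM + 1) of 8.54 ± 0.02 (percentile 100). Pou5f1, which encodes Oct4, stood at 1375 ± 65.3 CPM. Trim28, a co-repressor gene, stood at 1428 ± 41.3 CPM, and Dppa5a was the most abundant at 2915 ± 242 CPM, although 38.6% of its sequence recurs in other genes. Gdf3 (78.4 ± 9.98 CPM) was the lowest of this list in CPM, whereas Zfp281 was the lowest in TPM (61.3). All 20 naive pluripotency genes were expressed too, at a median of 6.91 ± 0.12 (percentile 100). The naive transcription factor genes Tfcp2l1 (684 ± 26.8 CPM), Esrrb (569 ± 26.1 CPM) and Zfp42 (487 ± 12.2 CPM) led this list in CPM. Dppa3 (11.6 ± 1.65 CPM) and Gbx2 (10.3 ± 4.72 CPM) were its lowest members in CPM. In TPM, Spp1 (715), Zfp42 (714) and Klf2 (541) led it. Of the genes linked to primed pluripotency, 16 of 18 were expressed, at a median of 5.04 ± 0.10 (percentile 98.4). Etv5 (582 ± 27.1 CPM) and the DNA methyltransferase genes Dnmt3b (290.4 ± 9.21 CPM) and Dnmt3a (169.5 ± 3.62 CPM) were high, whereas the epiblast marker Fgf5 stood at 0.232 ± 0.00360 CPM and Cer1 had no count.

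Lineage markers lay below the core pluripotency genes as groups, with exceptions such as keratin and laminin genes. The median log2(CPM + 1) was 0.41 ± 0.02 for mesoderm (4 of 17 genes expressed), 0.24 ± 0.06 for definitive endoderm (3 of 14) and 0.65 ± 0.28 for neuroectoderm (8 of 17). It was 1.97 ± 0.02 for trophoblast (10 of 17) and 0.78 ± 0.10 for extraembryonic endoderm (9 of 19). Their percentiles among random lists were 10.4, 6.34, 16.1, 41.4 and 17.7, in the same order. The mesoderm receptor gene Kdr stood at 5.29 ± 1.68 CPM and Eomes at 5.05 ± 0.541 CPM. In the endoderm list Krt19 (64.6 ± 7.08 CPM) exceeded Hhex (7.74 ± 0.302 CPM) and Gata4 (5.05 ± 1.02 CPM), and Alb and Afp had no count. Tubb3 (45.6 ± 0.339 CPM) and Nes (30.9 ± 1.71 CPM) led the neuroectoderm list, where Olig2 and Dcx had no count. Peg10 (331 ± 51.5 CPM) and Krt8 (164 ± 6.62 CPM) led the trophoblast list and the laminin gene Lamc1 (596 ± 40.9 CPM) the extraembryonic endoderm list, while the trophoblast gene Tpbpa and the yolk sac gene Ttr had no count. The median of the core pluripotency list exceeded that of the 77 lineage genes by 7.99 ± 0.16 on the log2 scale (7.88 in replicate 1, 8.10 in replicate 2), at percentile 100 of random pairs of lists. The naive list exceeded the primed list by 1.87 ± 0.22 (1.71 and 2.02), at percentile 82.8, so this difference lay inside the range of random pairs (-3.67 to 3.61). Genes with no count in either library were not detectable at this depth.

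**Figure D2:**
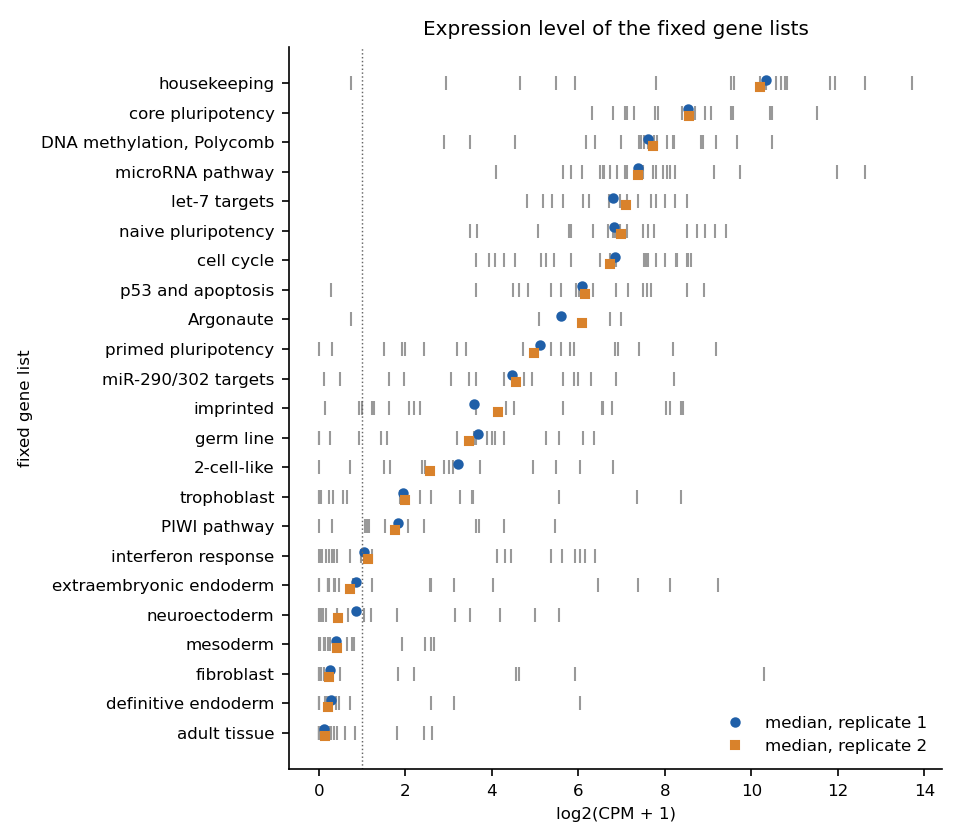
Level of each member (grey ticks, log2 of CPM + 1, mean of both libraries) of the 23 gene lists fixed before the data were examined, with the list median in replicate 1 (blue circles) and replicate 2 (orange squares); the dotted line marks 1 CPM. The core pluripotency median lies at 8.54 and the mesoderm median at 0.41.

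Genes of early embryonic and germ cells were present at low to moderate levels. Of the 2-cell-like genes, transcripts of the cleavage-stage embryo that appear in a small share of embryonic stem cells, 12 of 14 were expressed, with a median of 2.89 ± 0.47 (percentile 63.1). Zscan4f (147 and 72.6 CPM in replicates 1 and 2), Zscan4c (64.6 ± 28.9 CPM) and Zscan4d (43.8 ± 18.9 CPM) were the most abundant, and their values are uncertain one by one because 49.6 to 86.8% of their sequence recurs in other genes. Of the germ line genes, 13 of 17 were expressed (median 3.57 ± 0.14, percentile 76.9), led by the receptor gene Kit (80.9 ± 3.56 CPM), Tex19.1 (67.8 ± 4.92 CPM) and Tfap2c (46.1 ± 8.30 CPM). Fibroblast markers, which feeder cells would bring, had a median of 0.25 ± 0.01 with 6 of 16 expressed (percentile 5.89). Fn1 was an exception at 1252 ± 12.1 CPM, Vim stood at 60.1 ± 5.26 CPM, and Col3a1 and Lum had no count. Genes of adult tissues had the lowest median, 0.13 ± 0.01, with 3 of 20 expressed (percentile 2.05).

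Targets of microRNAs were read as levels only, since no unmodified cells were analysed here. Listed targets of the miR-290 cluster, the main microRNAs of mouse embryonic stem cells, had a median of 4.51 ± 0.05 with 14 of 16 expressed (percentile 92.7). Ei24 (297 ± 2.52 CPM), the cell cycle inhibitor gene Cdkn1a (115 ± 9.38 CPM) and Epas1 (77.4 ± 1.70 CPM) were the most abundant, and Dkk1 had 5 and 1 counts in replicates 1 and 2, below the floor in replicate 2. All 15 listed let-7 targets were expressed, at a median of 6.95 ± 0.21 (percentile 100). Igf2bp1 (364 ± 14.3 CPM), Trim71 (301 ± 21.2 CPM) and Hmga1 (255 ± 3.21 CPM) led in CPM, although 55.0% of the Hmga1 sequence recurs in other genes. The p53 and apoptosis list had 17 of 18 genes expressed (median 6.12 ± 0.06, percentile 99.97), with Mcl1 at 478 ± 20.8 CPM, Trp53 at 363 ± 11.8 CPM and Bcl2 at 0.287 and 0.134 CPM in replicates 1 and 2 (10 and 4 counts). All 22 cell cycle genes were expressed (median 6.80 ± 0.08, percentile 100), led by Cdk4 at 387 ± 6.67 CPM. The lowest was Cdkn1c in replicate 1 (5.55 CPM, against 17.3 CPM in replicate 2) and Cdkn2a in replicate 2 (14.9 CPM).

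Chromatin regulators were abundant, and genes of the interferon response were not. All 20 genes of DNA methylation and Polycomb repression were expressed (median 7.67 ± 0.09, percentile 100), including Tet1 (751 and 864 CPM in replicates 1 and 2) and Uhrf1 (576 ± 2.63 CPM). Of the interferon response genes 10 of 20 were expressed (median 1.09 ± 0.07, percentile 21.3). The RNA sensor gene Ddx58 (82.6 ± 12.2 CPM) and its adaptor Mavs (65.2 ± 6.23 CPM) were among the highest, and Ifnb1 had no count. Of the imprinted genes, expressed from 1 parental allele, 15 of 20 were expressed (median 3.86 ± 0.40, percentile 85.3), led by Rian (339.5 ± 12.8 CPM), Peg10 (331 ± 51.5 CPM) and Grb10 (279 ± 2.49 CPM). The housekeeping list had a median of 10.27 ± 0.09 (percentile 100) with 17 of 18 expressed. The exception was Hprt (GRCm38 chromosome X, 52988137 to 53021659, plus strand), with 25 and 18 counts or 0.661 ± 0.0807 CPM, a gene of purine salvage that was lost in a widely used derivative of the E14 line. In all, 14115 genes, 12530 of them protein-coding, reached 1 CPM in both libraries. The translation factor gene Eef1a1 (13525 ± 613 CPM) and the mitochondrial gene mt-Co1 (11792 ± 645 CPM) were the most abundant transcripts, followed by Hsp90ab1 and Hsp90aa1 (6361 ± 276 CPM).

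The comparison of the libraries with each other set the error of these levels. Across 19078 genes with at least 10 counts, log2(CPM + 1) correlated with a Pearson r of 0.996 and a Spearman rho of 0.992 across genes, which are not independent replicates. The median absolute log2 ratio was 0.12 over the 13553 genes with at least 100 counts, of which 151 differed more than 2-fold, 25 higher and 126 lower in replicate 2. The chi-square per degree of freedom was 9.83, so the libraries differed by more than sampling noise and were not merged into 1 sample, which does not show that they came from separate cultures. The two-sided exact binomial test with Benjamini-Hochberg adjustment called 4567 genes, 2102 higher and 2465 lower in replicate 2. This test compares the reads of these libraries, not conditions, and counts any spread above sampling noise. With the spread of these libraries included (common biological coefficient of variation 9.99%), edgeR's exact test called 87 genes, 22 higher and 65 lower. Higher genes thus made up 46.0% of the calls in the binomial test and 25.3% in edgeR's test.

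Among genes named by size of the difference, Polg2, which encodes the accessory subunit of the mitochondrial DNA polymerase, was the highest in replicate 2. It had 230 and 1741 counts, a log2 ratio of 3.14 ± 0.10 (counting SE) and an adjusted p of 3.58e-45 in edgeR's exact test; its exons overlap another gene. Cox7b2 (2.57), Platr12 (2.04), Scand1 (1.70) and the imprinted growth inhibitor gene Cdkn1c (1.63) followed in log2 ratio. Lower in replicate 2 were Zfp264 (-2.38), Tuba3b (-2.19), 4933427D06Rik (-2.15), Duxbl2 (-1.90), Zfp951 (-1.89) and Xlr3a (-1.75). Duxbl2, Xlr3a and Tuba3b share sequence with other genes (100, 44.8 and 29.5% of 50-base stretches), so their values are uncertain. Duxbl2 did not pass edgeR's exact test (adjusted p = 0.0846), and the other 10 of these 11 genes did.

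**Figure D3:**
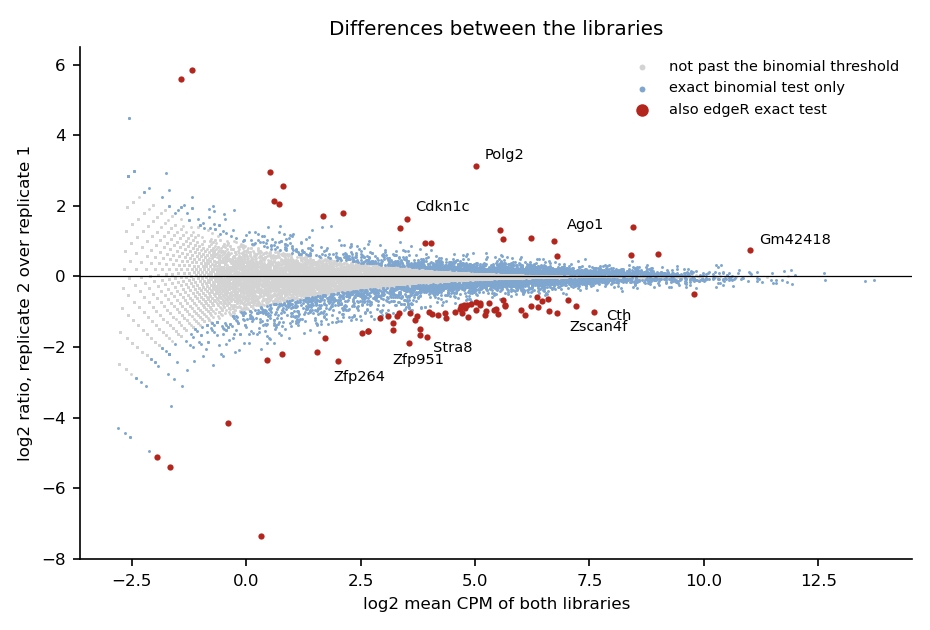
Log2 ratio of replicate 2 over replicate 1 against the log2 mean CPM for the 19078 genes with at least 10 counts; grey, not past the threshold; blue, past the exact binomial test only; red, past edgeR's exact test as well. Of the 87 red points, 65 lie below 0, and Ago1 lies at 0.99.

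The 2-cell-like genes were lower in replicate 2 as a group. Their median log2 ratio was -0.80, at percentile 0 of 10000 random lists matched on expression. Of 13 tested members 11 were lower, none was higher and 2 were not called, and 12 were lower when adjusted over the list alone; edgeR's exact test called 4. Zscan4f was lower by a log2 ratio of -1.02, Zscan4c of -0.95 and Zscan4d of -0.91. The PIWI pathway list had a median of -0.34 (percentile 0.87) with 3 of 11 members lower and none higher, also 3 when adjusted over the list alone, and none in edgeR's exact test. Those 3 were Mael (-0.39), Mov10l1 (-0.52) and Piwil2 (-0.18); with only members of at least 100 counts the median was -0.18 (percentile 9.43), inside the random range. Housekeeping genes had a median of -0.10 (percentile 0.09; 10 lower, 2 higher of 18) and naive pluripotency genes one of 0.08 (percentile 98.9; 12 higher, 4 lower of 20). Adjusted over the list alone, 12 and 16 were called, and edgeR's exact test called none in either list. Called shares of similar size also occurred in lists with medians inside the random range, such as core pluripotency and DNA methylation and Polycomb. With the housekeeping and naive lists restricted to members with little shared sequence, the percentiles were 3.48 and 97.1, inside the central 95%. The medians of the other 19 lists, from -0.33 for definitive endoderm to 0.08 for mesoderm, lay inside the central 95% of matched random lists. About 1 list in 20 leaves this range by chance if its genes vary independently. Related genes may not, so the rate for these lists is not known.

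**Figure D4:**
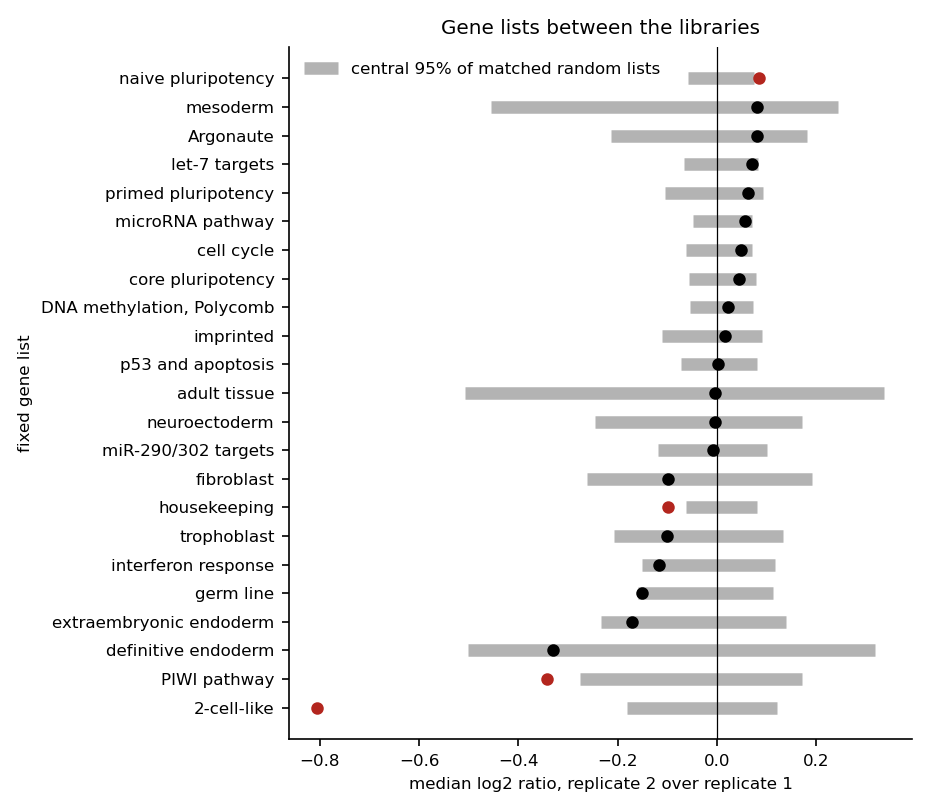
Median log2 ratio of replicate 2 over replicate 1 for each fixed gene list (points), with the central 95% of 10000 random lists matched on expression (grey bars); red points lie outside it. The 2-cell-like list lies at -0.80 and the PIWI list at -0.34.

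Imprinted genes differed between the libraries in both directions. The median of their 19 tested members was 0.02 (percentile 67.7), but their mean absolute log2 ratio was 0.53, at percentile 99.8 of matched random lists. The spread was not particular to them, since 4 other lists also lay above the central 95% on this measure: 2-cell-like (percentile 100), naive pluripotency (98.6), cell cycle (98.2), which shares Cdkn1c with the imprinted list, and let-7 targets (98.1). The exact binomial test called 4 imprinted genes higher and 5 lower, and 10 when adjusted over the list alone. In edgeR's exact test 2 were called, Cdkn1c (1.63) and Nnat (2.95). Nnat, with 11 and 76 counts, was singled out after its value was seen. The mean absolute ratio was 0.36 (percentile 99.7) over the 15 imprinted genes with at least 100 counts, which leave out Nnat but keep Cdkn1c. A mean gives single large ratios much weight, and it was not computed without both genes. The spread of the list may therefore rest on them.

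Along the genome, the medians of the 20 chromosomes from 1 to 19 and X ran from -0.05 to 0.05, but neighbouring genes differed together in places. This scan was added after the values were seen. The last 7 genes of chromosome 3 with at least 100 counts, at GRCm38 157534160 to 159529955, were all lower in replicate 2, with log2 ratios from -0.99 to -0.65 and a median of -0.84. They were Zranb2 (-0.69), the cystathionine gamma-lyase gene Cth (-0.99), Gm43314 (-0.92), Ankrd13c (-0.84), the splicing factor gene Srsf11 (-0.65), Lrrc40 (-0.84) and Depdc1a (-0.89). All 7 passed the exact binomial test, and 5 of them passed edgeR's exact test, with adjusted p from 1.38e-09 for Cth to 0.00193 for Zranb2. Gm43314 lies within Cth, so these values are not independent, and 60.8% of the 50-base stretches of Depdc1a recur in other genes. The 20 genes before them on the chromosome had a median of 0.08 (quartiles -0.07 and 0.18).

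**Figure D5:**
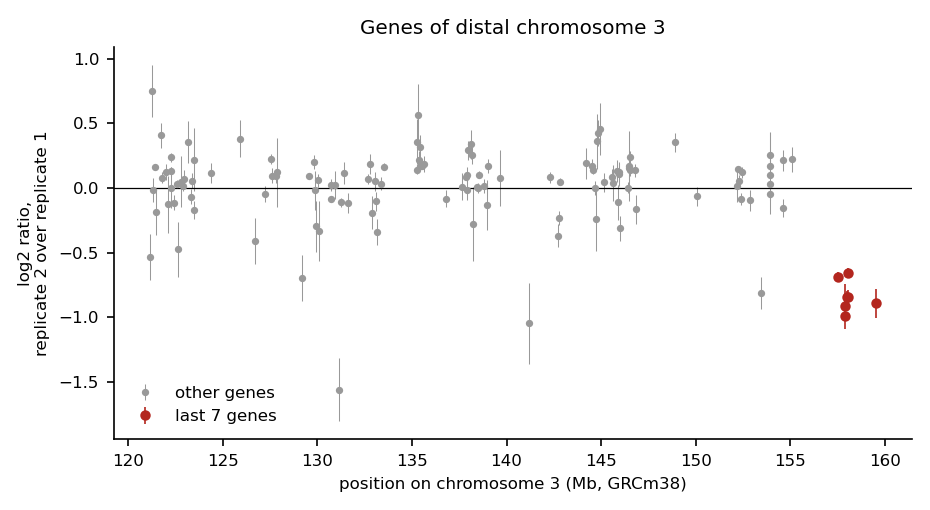
Log2 ratio of replicate 2 over replicate 1 (bars, counting SE) against position on distal chromosome 3 for genes with at least 100 counts. The last 7 genes (red) lie between -0.99 and -0.65.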

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

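For the list differences, removal of the GC and length trend and the limit to little shared sequence were chosen after seeing the data; for the count of calls, removal of the trend (3903 calls) was planned. The list differences kept their side of the central 95% with DESeq2 size factors, library totals and a pseudocount of 5, and no called result changed direction. The 2-cell-like median stayed below the random range in every alternative that left it at least 3 members; too few share little sequence. Each library alone kept every level within the SD of the pair, which a pair of libraries fixes, so this says nothing about stability. Leaving the mitochondrial and 20 most abundant genes out of the total put Ago2 at 140 CPM; this total is smaller by construction. With TPM the Ago1 and Ago2 share was 91.0%. Some list percentiles also moved with TPM. They fell from 95.9 to 79.5 for Argonaute and from 85.3 to 66.3 for imprinted genes. They rose from 63.1 to 84.6 for 2-cell-like and from 41.4 to 52.7 for trophoblast genes. The 4567 calls of the binomial test became 87 with edgeR's exact test, which adds the spread of these libraries. At 5 CPM fewer listed genes counted as expressed by construction: 4 for PIWI, 7 for 2-cell-like, 6 for trophoblast, 5 for neuroectoderm and 0 for mesoderm and adult tissue; at 1 TPM neuroectoderm also had 5. The core minus lineage difference was 9.37 and 6.11 with pseudocounts of 0.1 and 5, 8.44 in TPM and 6.76 with means, and naive minus primed was 1.32 in TPM and 2.42 with means. Between the libraries, the PIWI median moved inside the random range at 100 counts (-0.18), as did naive (0.078) and housekeeping (-0.11) with little shared sequence, where fewer members remain. Primed (0.10) moved outside it without the GC trend, and interferon without the GC trend (-0.15) and with little shared sequence (-0.20); the cause was not tested. No paired analysis was possible because there is 1 group. The other strand could not be tried, since the files hold 1 column, and the between-library results need both libraries. Low counts limit single values such as Ago4 and Hprt.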

Other observations

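Several further genes differed between the libraries; those named here were picked after their values were seen. Lower in replicate 2 were Stra8, which acts at the entry into meiosis, by a log2 ratio of -1.66 (736 and 199 counts, edgeR exact test adjusted p = 2.10e-07), and the meiotic gene Hormad2 by -1.59 (adjusted p = 0.00251). Higher in replicate 2 were the imprinted genes Zdbf2 (1.10, adjusted p = 7.30e-09) and Phlda2 (1.07, adjusted p = 6.55e-07). Phlda2 lies in a row with Cdkn1c (1.63) and Slc22a18 (0.58) on chromosome 7, GRCm38 143458339 to 143503150. Slc22a18 passed the exact binomial test (adjusted p = 0.00129) but not edgeR's exact test (adjusted p = 1). Kcnq1ot1, the non-coding RNA that silences this cluster in cis, was lower (-0.44, exact binomial test adjusted p = 2.68e-06), but not past edgeR's exact test. Gm42418, a locus that overlaps ribosomal RNA sequence, was higher in replicate 2 (1547 and 2599.8 CPM, log2 ratio 0.75, adjusted p = 7.81e-06). The Y-linked genes Ddx3y (104 ± 7.81 CPM) and Eif2s3y (76.7 and 73.3 CPM) were present in both libraries, and Xist had 9 and 14 counts.

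Of the runs of at least 5 neighbouring genes with log2 ratios below -0.5, the 6 outside the end of chromosome 3 lay in clusters of related genes. They include Zscan4 genes on chromosome 7 (median -0.95), Tdpoz genes on chromosome 3 (median -0.95) and Pramef genes on chromosome 4 (median -1.17). In these clusters a median of 13.4 to 86.8% of 50-base stretches recurs elsewhere, so single values are uncertain. In the other direction the longest run had 3 genes, the Cdkn1c row, and shuffled gene orders gave runs of up to 4.

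3 patterns were weighed, all noticed in these data first; the tests of neighbouring genes of Ago1, of summed families and of the end of chromosome 3 were chosen after the result was seen. The design has 1 group, so no biological explanation named by the design was tested.

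Ago1 was higher in replicate 2 by a log2 ratio of 0.99. The tables argue against a gain of the whole region, since the 32 neighbouring genes within 1 Mb had a median of -0.037 (-0.44 to 0.24). They argue against a bias of GC content and length, since the ratio was 1.02 with the trend removed, and against reads shared with other Argonaute genes, since 1.53% of its 50-base stretches recur elsewhere. A difference between edited alleles or clones may underlie it; this hypothesis was not tested, since counts per gene do not show alleles.

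The 2-cell-like genes were lower in replicate 2. With the GC and length trend removed the median was -0.86 (percentile 0), which argues against that trend as the cause. Reads of 1 changed family counted for the others would leave the remaining families near 0, but with counts summed in 9 families that share no stretch with each other the median was -0.78, from -1.10 to -0.56. How far near-identical copies outside the list add to each value cannot be told apart, because only 2 members, Tmem92 and Arg2, share under 5% of their stretches (median -0.70). A smaller share of cells in a 2-cell-like state in replicate 2 may underlie the pattern and was not tested.

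The end of chromosome 3 was lower in replicate 2 over 7 genes. No run longer than 5 genes arose in 1000 shuffled gene orders, which argues against a chance run of independent genes. The run counts Gm43314, which lies within Cth, and Depdc1a, which shares sequence, so fewer than 7 genes are independent. Shuffling also breaks any tie between neighbours, and long runs occurred in clusters of related genes too, such as 9 genes around Tdpoz3. The median stayed at -0.91 with the GC and length trend removed, and the median share of stretches found in other genes was 0%, with 60.8% for Depdc1a, which argues against those explanations. A candidate explanation is loss of 1 copy of this segment in most cells of replicate 2, which predicts a ratio near -1 for its other genes too. No reference sample was analysed, so the ratio cannot show which of the libraries changed at this segment. The 10 genes of the segment that were too low for the run had 270 and 128 counts in sum. Wls, among them, lies past the last gene of the run, so the segment is taken beyond it. Their summed log2 ratio was -0.85 (95% interval -1.17 to -0.55), a range that includes -1. It also includes smaller drops, such as those of Zranb2 (-0.69) and Srsf11 (-0.65) in the run. The range therefore cannot set a loss of 1 copy apart from another shared change of these genes. The hypothesis of a loss was formed on the same data and needs DNA to test.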
